A study of Mus musculus with 6 samples.

How the data were processed

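miRNA sequencing was done on hippocampal neural stem cells of male mice at postnatal day 3, with 3 libraries from offspring of dexamethasone-injected dams (GDE) and 3 from offspring of saline-injected dams (Control). Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the MGIEasy Small RNA kit. The submitters' processing notes name Bowtie2 and the mm10 build, with no version or role. Further steps, such as adapter trimming, the assignment of reads that match several miRNAs and any collapsing by molecular identifiers, are not given in the sources used here. The group and replicate number of each library were taken from its title, where IUGR stands for GDE and Normal for Control per the design text.

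The deposited values were read as RPM from the values themselves, since per the file headers the 6 columns are called expression only. In each library the low values were whole multiples of 1 step, between 0.0807 and 0.0851 RPM, and 100% of the nonzero values came out as whole tags within a tolerance of 0.1 tags. The step gives the depth, about 11751000 to 12385000 tags per library, while the tags in the table came to 2927136 to 3343808. So the RPM deposited by the authors sum to 241370 to 277888 per library, and the rest of the tags are not in the table. A count of 0 in a library allows up to 3 tags, or about 0.25 RPM. Reads from PCR without known molecular identifiers are not independent molecules. Of the 1522 rows, 179 had the values of another row in all libraries, 19 of them at a mean of at least 1 RPM, as happens where precursors share 1 mature sequence.

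The design fixed before the data were examined had edgeR's quasi-likelihood test for counts and limma for normalized values. As the values were RPM, limma 3.58.1 in R 4.3.3 was the main test, with a trend on log2(RPM + 1), no further scaling, and miRNAs of at least 1 RPM in 3 or more libraries (649, of which 562 had a miRBase name). The Benjamini-Hochberg threshold was 0.05, tests were two-sided, and log2 folds are GDE minus Control on the log2(RPM + 1) scale, which understates the change of low miRNAs. On the recovered tags, edgeR 4.0.16 called 2 miRNAs, and DESeq2 1.42.0 and limma-voom were run beside it. Lists, genomic clusters and host gene sets were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and the lists with fry. Clusters joined precursors within 10 kb on 1 strand and needed 3 tested miRNAs. Of the 1147 named rows, 1101 were placed on a precursor of GENCODE M21 (GRCm38, the assembly called mm10), and coordinates are from there. Arm usage was the log2 ratio of the 5p over the 3p arm per precursor, tested in limma. Single values and library composition were tested by exact permutation. Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3 was used.

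Named miRNAs followed a rule fixed beforehand. It took both arms of miR-335, the 10 most abundant miRNAs, up to 12 in each direction past the threshold whose groups did not overlap, filled up to 5 by lowest p where fewer passed, and the 4 most abundant members of each list; some members of lists far from the threshold are not printed. Predicted miRNAs are counted and, with 1 exception said where it stands, not named.

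The tests were tested on simulated data with the means and spread of these libraries. In the simulated comparison of GDE and Control, over 650 miRNAs, limma recovered 61.1% of the miRNAs changed 2-fold and 97.9% of those changed 4-fold, and 5.6% of its calls were unchanged ones. Many miRNAs were changed at once in this simulation, which makes the adjusted threshold easier to pass. With few changed miRNAs a lower share would be recovered, so these shares do not give the power of the real comparison. For arm ratios 65% of the precursors changed 4-fold were recovered over 155. Alternatives covered the scaling, the pseudocount (0.1 and 10), the filter, the tool, a replicate block and leaving out each library in turn. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 39.1 to 139.4 between pairs, so no library was counted as a repeat of another. On the first principal component Control replicate 1 lay farthest out, and on the second GDE replicate 3.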

Results

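Small RNA was sequenced from neural stem cells (NSCs, the dividing precursors of neurons and glia) that had been isolated from the hippocampus of male C57BL/6J mice at postnatal day 3. The 2 groups differed in what the pregnant dams had received. In the exposed group, GDE below, dams were injected with dexamethasone, a synthetic glucocorticoid, at 1 mg/kg per day from E14.5 to E18.5 (embryonic days). In the Control group the injections held saline. The library titles call the exposed group IUGR and the Control group Normal, and the design text equates these names. Each group had 3 libraries, and the design text states that these came from independent litters. The table held 1522 mature miRNAs, 1147 with a miRBase name and 375 predicted ones, as RPM, reads scaled to the depth of the library. Whole tags could be recovered from these values. Each library rested on about 11751000 to 12385000 tags in all, of which 2927136 to 3343808 were assigned to the miRNAs of the table. Between 1273 and 1332 miRNAs were detected per library.

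The study title names miR-335-3p, so this miRNA was examined first. Its precursor Mir335 lies at chromosome 6, 30741299 to 30741396 on the plus strand (GRCm38), in an intron of Mest, an imprinted gene expressed from the paternal copy. miR-335-3p was at 160.2 ± 17.1 RPM in GDE and at 344.5 ± 155.8 RPM in Control (mean ± SD, n = 3 each). The 3 GDE libraries held 142.2, 162.4 and 176.1 RPM, and all of them lay below the 3 Control libraries at 509.8, 323.6 and 200.2 RPM. The log2 fold of GDE over Control was -1.003 (SE 0.32), so the level was lower in the libraries titled IUGR. The title of the study speaks of targeting this miRNA in exposed offspring, and the direction given here rests on the library titles and the design text alone. It did not pass the threshold over all 649 tested miRNAs (limma, adjusted p = 0.551; 0.211 to 0.822 over the alternatives). Adjusted over the list alone, which the study itself chose and which is therefore no independent evidence, 1 of the 2 arms passed, with an adjusted p of 0.0298 in limma. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The 5p arm of the same precursor was at 154.9 ± 7.26 RPM in GDE and at 235.9 ± 130.7 RPM in Control, with overlapping groups and a log2 fold of -0.47 (SE 0.35; limma, adjusted p = 0.702; exact permutation p = 0.4). Control replicate 1 set part of both differences. Without it the log2 fold of miR-335-3p was -0.67 and that of miR-335-5p was -0.05.

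**Figure D1:**
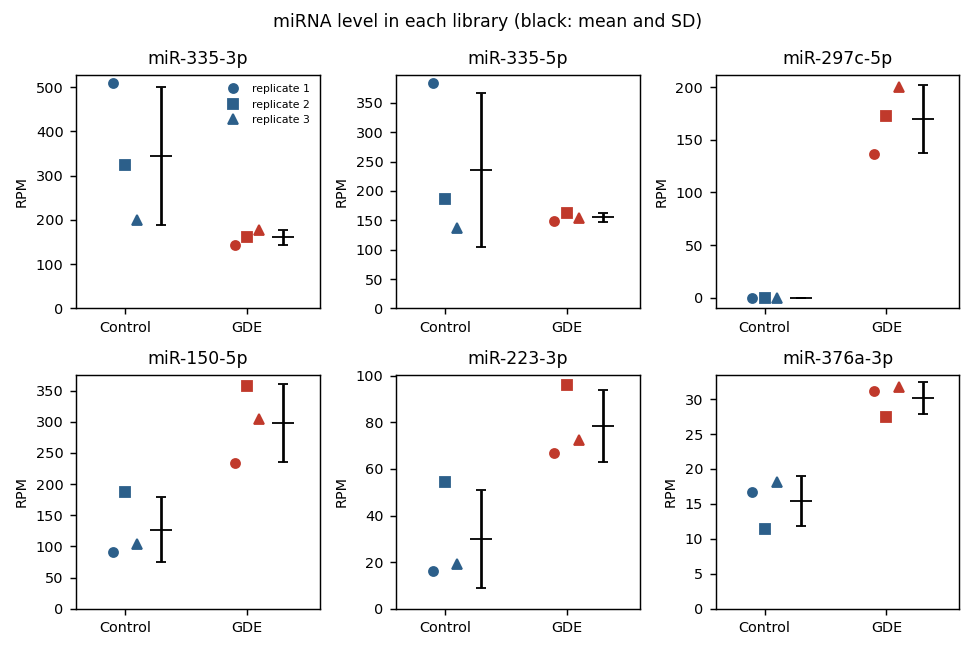
RPM of 6 miRNAs in each library, with symbols for the replicates of a group and the mean and SD in black. miR-297c-5p lies between 136.2 and 200.3 RPM in the GDE libraries and at the baseline in Control, whereas miR-335-3p is lower in all 3 GDE libraries and Control replicate 1 stands highest for both arms of miR-335.

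Over all tested miRNAs, 2 differed between the groups in limma at an adjusted p under 0.05, 1 higher and 1 lower in GDE. The higher one was miR-297c-5p, a member of the large family of near-identical miRNAs in an intron of Sfmbt2. It was at 169.7 ± 32.1 RPM in GDE (n = 3) and nearly absent from Control. GDE libraries held 1632 to 2429 tags each, 6100 in sum, while the Control libraries held 1 tag in sum and 2 of them none (limma, adjusted p = 4.72e-07). The exact permutation p was 0.1, as for miR-335-3p, since 3 against 3 libraries allow no smaller value. The ratio of the group sums was 6142, with a 95% counting interval of 1102 to 242647 (exact binomial). Intervals of this kind cover counting error only. Mir297c lies at chromosome 2, 10509016 to 10509113 (GRCm38). The lower one was a predicted miRNA without a miRBase name, given here after its values were seen because it completes the count. It was at 0.196 ± 0.174 RPM in GDE and at 6.64 ± 1.82 RPM in Control (limma, adjusted p = 0.00188). limma-voom did not call this predicted miRNA. The filter of at least 100 tags in 3 libraries removed it, as it had too few tags, so it was not tested there.

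Of the 649 tested miRNAs, 56 had an unadjusted p under 0.05 in limma, 26 higher and 30 lower in GDE, where 32.5 would be expected by chance. The groups did not overlap for 95 miRNAs, or 14.6%, against 10% by chance, 30 of them higher and 65 lower in GDE. The lowest adjusted p after those past the threshold was 0.478. Named by lowest p and not past the threshold, those higher in GDE included 2 miRNAs of blood leukocytes. miR-150-5p, abundant in lymphocytes, was at 298.4 ± 62.5 RPM in GDE and 126.8 ± 52.4 RPM in Control (log2 fold 1.28, SE 0.31; limma, adjusted p = 0.51). miR-223-3p, a miRNA of myeloid cells, was at 78.3 ± 15.5 against 30.0 ± 21.2 RPM (log2 fold 1.55, SE 0.43; limma, adjusted p = 0.551), and it passed the threshold without Control replicate 2 (limma, adjusted p = 0.0329; range over the alternatives 0.0329 to 0.816). miR-376a-3p, of the Dlk1-Dio3 imprinted locus, was at 30.1 ± 2.29 against 15.4 ± 3.55 RPM (log2 fold 0.95; limma, adjusted p = 0.51; DESeq2, adjusted p = 0.0149; range over the alternatives 0.0149 to 0.816). miR-669c-5p, whose precursor lies next to Mir297c at chromosome 2, 10509296 to 10509404, was at 11.1 ± 8.36 RPM in GDE and at 0.855 ± 0.928 RPM in Control, with GDE replicate 1 at 2.00 and Control replicate 1 at 1.91 RPM. Among the alternatives it passed only without GDE replicate 1 (limma, adjusted p = 0.0133; range 0.0133 to 0.822). Among those lower in GDE, also not past the threshold, miR-672-5p was at 204.7 ± 17.6 against 300.1 ± 41.8 RPM and miR-296-3p at 90.0 ± 67.2 against 253.9 ± 68.2 RPM. miR-3067-5p was at 1.48 ± 0.336 against 3.78 ± 1.64 RPM, and miR-467a-3p at 2.70 ± 0.888 against 4.94 ± 0.528 RPM (limma, adjusted p = 0.551 for each of these 4).

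The 10 most abundant miRNAs included 2 arms of miR-9 and 4 members of the let-7 family, and the levels of these 10 in the groups lay close together. miR-9b-3p was at 9360 ± 104 RPM in GDE and 9307 ± 238 RPM in Control. miR-9-5p, which is enriched in neural progenitors, was at 8389 ± 209 against 8427 ± 357 RPM, and miR-9-3p at 7882 ± 718 against 7915 ± 369 RPM. For let-7c-5p the values were 8943 ± 183 and 9041 ± 237 RPM, for let-7b-5p 8281 ± 105 and 8407 ± 227 RPM, for let-7a-5p 7828 ± 195 and 8106 ± 186 RPM, and for let-7f-5p 7524 ± 110 and 7732 ± 238 RPM. miR-99a-5p stood at 8719 ± 161 and 8772 ± 191 RPM, miR-34a-5p at 7801 ± 383 and 7814 ± 152 RPM, and miR-26a-5p at 7760 ± 275 and 7689 ± 188 RPM. None of these 10 passed the threshold in limma. Their narrow spread was itself unusual. The 18 miRNAs above 5000 RPM held 53.7% of all RPM and had a median within-group SD of 0.05 on the log2 scale, against 0.19 for the 34 miRNAs between 1000 and 5000 RPM. The recovered tags of miR-9b-3p lay between 111884 and 112346 in all 6 libraries, with a variance over mean of 0.319. For the other 19 of the 20 most abundant miRNAs that ratio lay between 9.18 and 587.7. Whether a limit on the tags counted per miRNA acted on these values was not settled, so close levels among them, or in the let-7 and neural progenitor lists, do not show that the groups were equal.

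**Figure D2:**
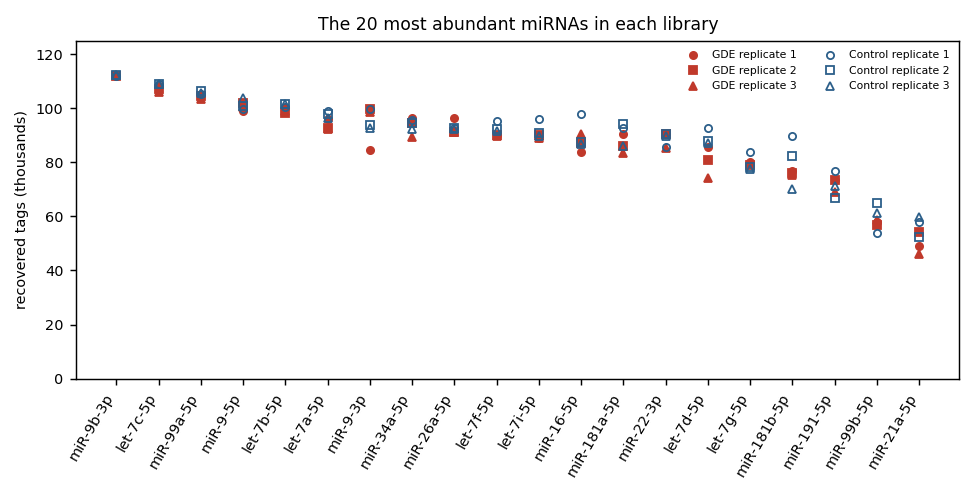
Recovered tags (axis in units of 1000) of the 20 most abundant miRNAs in each of the 6 libraries, with GDE in filled red and Control in open blue symbols. The tags of miR-9b-3p lie between 111884 and 112346 in all libraries and the spread widens toward less abundant miRNAs.

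Lists of miRNAs fixed before the data were examined were then compared. Of 21 lists, 19 had tested members, and 5 passed at an adjusted p under 0.05 in camera with a preset correlation of 0.01, 4 of them toward higher values in GDE. All 5 calls were lost with an estimated correlation (adjusted p = 0.619 for each). No list passed in the directional fry test, where the lowest adjusted p was 0.375 and 1 list had an unadjusted p under 0.05. The mixed fry test, for changes in either direction, gave unadjusted p of 6.92e-06 for the Sfmbt2 intron list, which holds miR-297c-5p. It gave 0.00466 for the Dlk1-Dio3, 0.00717 for the endothelial and mural, 0.0221 for the neuron-enriched and 0.0399 for the microglia and leukocyte list. These mixed p values were not adjusted over the lists. All 5 calls were also lost without Control replicate 1, with adjusted p between 0.054 and 0.268 in camera.

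In the list of the Dlk1-Dio3 imprinted locus, a maternally expressed miRNA cluster active in developing brain, 20 of 31 tested members had a positive and 11 a negative log2 fold, with a median of 0.14 (camera, adjusted p = 0.00346; adjusted p = 0.619 with an estimated correlation). None of the 31 passed the threshold over all miRNAs or adjusted over the list alone. Of its 4 most abundant members, miR-376a-3p was higher in GDE and the other 3 were lower. miR-127-3p was at 64.6 ± 6.63 RPM in GDE against 80.4 ± 10.7 RPM in Control, miR-379-5p at 46.3 ± 13.5 against 69.4 ± 8.72 RPM and miR-411-5p at 42.9 ± 2.32 against 52.8 ± 9.91 RPM. The call was lost without GDE replicate 1 (camera, adjusted p = 0.0594) and without Control replicate 1 (adjusted p = 0.268). Of 28 genomic clusters, 1 passed, and it lay in this locus. It ran from Mir379 to Mir410 at chromosome 12, 109709060 to 109743795, with 17 positive and 7 negative log2 folds and a median of 0.24 (camera, adjusted p = 0.00228; adjusted p = 0.933 with an estimated correlation). Without GDE replicate 1 or without Control replicate 1, 0 clusters passed, and without Control replicate 3 there were 2, the added one being Mir466m to Mir467b of the Sfmbt2 intron.

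The neuron-enriched list had 12 of 20 members with a positive log2 fold and a median of 0.06 (camera, adjusted p = 0.0373; adjusted p = 0.619 with an estimated correlation). No member passed the threshold over all miRNAs or adjusted over the list alone. Of its members 4 also belong to the Dlk1-Dio3 locus, and among the other 16 there were 8 positive folds with a median of 0.01. The 4 most abundant members had close levels in the groups. miR-149-5p was at 1299 ± 17.3 RPM in GDE against 1426 ± 207 RPM in Control, miR-129-5p at 896.8 ± 182.9 against 877.4 ± 168.3 RPM, miR-128-3p at 593.5 ± 57.5 against 659.9 ± 116.5 RPM and miR-153-3p at 554.2 ± 61.3 against 513.1 ± 94.5 RPM. The call stood without GDE replicate 2 and without GDE replicate 3 and was lost without any other library, with adjusted p of up to 0.29 in camera. It was also lost with a replicate block.

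The list of the Sfmbt2 intron was made by name, from all miR-297, miR-466, miR-467 and miR-669 copies. It had a negative log2 fold in 41 of 46 tested members, with a median of -0.30 and a mean of -0.08, the latter raised by miR-297c-5p (camera, toward lower values in GDE, adjusted p = 0.0168; adjusted p = 0.619 with an estimated correlation). miR-297c-5p was the only member past the threshold, over all miRNAs and adjusted over the list alone, and it was higher. miR-467a-5p was at 1111 ± 42.9 RPM in GDE against 1380 ± 171 RPM in Control and miR-297a-5p at 230.2 ± 27.1 against 302.4 ± 63.4 RPM. miR-669b-5p stood at 243.1 ± 10.9 and 264.5 ± 48.9 RPM, and miR-467e-5p at 238.7 ± 24.9 and 275.6 ± 19.8 RPM. These copies are nearly identical, and 13 of the tested members carried exactly the values of another member, so their values are uncertain and not independent; 39 distinct ones remained, 34 of them negative. The call was lost without GDE replicate 2 (camera, adjusted p = 0.067), GDE replicate 3 (0.0817), Control replicate 1 (0.054) or Control replicate 2 (0.192). Sets made by position did not pass. The host gene set of Sfmbt2 had 25 negative folds among 28 tested miRNAs (camera, adjusted p = 0.234). The clusters Mir466m to Mir467b and Mir467e to Mir669h of this intron had adjusted p of 0.105 and 0.772 in camera.

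Lists of miRNAs of cell types other than neural ones were compared because a hippocampal preparation could hold such cells. The microglia and leukocyte list had 6 positive and 3 negative log2 folds with a median of 0.23 (camera, adjusted p = 0.0263; adjusted p = 0.619 with an estimated correlation). Adjusted over the list alone, 2 members were higher in limma, against 0 over all miRNAs. Its most abundant member, miR-21a-5p, went the other way, at 4155 ± 398 RPM in GDE against 4719 ± 442 RPM in Control, with miR-146a-5p at 1889 ± 175 against 1628 ± 321 RPM and miR-342-3p at 205.0 ± 14.9 against 198.8 ± 21.9 RPM. The call was lost without GDE replicate 2 (camera, adjusted p = 0.0697), GDE replicate 3 (0.0591), Control replicate 1 (0.2) or Control replicate 3 (0.0536). The endothelial and mural list had 8 positive and 2 negative log2 folds with a median of 0.33 (camera, adjusted p = 0.00346; adjusted p = 0.619 with an estimated correlation), with 0 members past the threshold over all miRNAs or adjusted over the list alone. The 2 negative members, miR-199a-3p and miR-199b-3p, carried exactly the same values, so they are not independent. miR-126a-3p, of endothelial cells, was at 333.8 ± 103 against 271.8 ± 55.0 RPM, miR-143-3p, of smooth muscle, at 73.7 ± 13.7 against 70.6 ± 9.91 RPM, miR-199a-5p at 40.7 ± 5.06 against 30.1 ± 6.33 RPM and miR-126a-5p at 18.4 ± 2.06 against 13.8 ± 2.24 RPM. This call was lost without GDE replicate 3 (camera, adjusted p = 0.147) or Control replicate 1 (0.054).

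**Figure D3:**
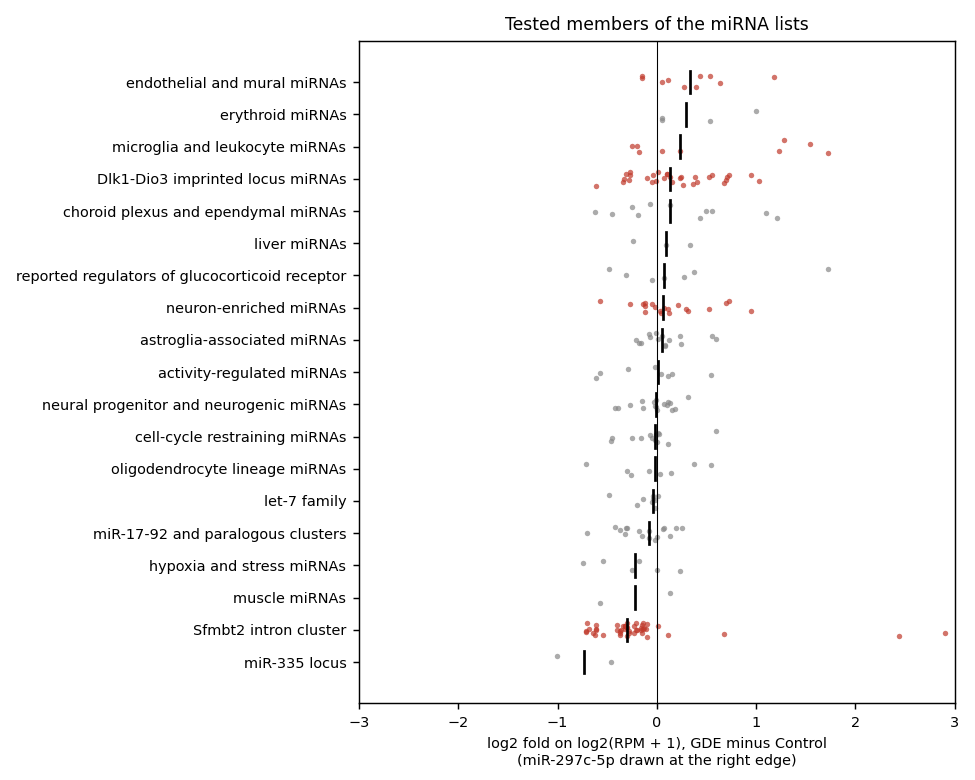
Log2 fold of each tested member of 19 miRNA lists, on log2(RPM + 1), GDE minus Control, with the median as a black line and the 5 lists past the threshold in camera with a preset correlation in red. miR-297c-5p, beyond the axis, is drawn at the right edge, and the medians lie between -0.74 for the miR-335 locus and 0.33 for the endothelial and mural list.

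The remaining 14 lists did not pass in camera. For the erythroid list the adjusted p was 0.0956, with miR-451a, the main miRNA of red cells, at 65.3 ± 8.06 RPM in GDE and 34.5 ± 16.5 RPM in Control, while miR-486a-5p, also of red cells, was at 15.6 ± 2.01 and 15.0 ± 1.14 RPM. Another member, miR-486b-5p, carried exactly the values of miR-486a-5p, so they are not independent. The erythroid list passed without GDE replicate 1 (camera, adjusted p = 0.0474), with at least 100 tags in 3 libraries (0.0474) and with no filter (0.0285). The miR-335 locus had an adjusted p of 0.146, and it passed without Control replicate 3 (camera, adjusted p = 0.0344) and with no filter (0.0379). With all libraries and the main filter, both lists had an adjusted p = 0.619 with an estimated correlation. In the choroid plexus and ependymal list (adjusted p = 0.254) members lay on both sides, and this was the 1 list with an unadjusted directional fry p under 0.05. miR-204-5p, abundant in choroid plexus, was at 682.0 ± 294.5 against 333.0 ± 182.3 RPM, and miR-34c-3p and miR-34b-3p, of ciliated cells, were at 285.5 ± 46.2 against 443.1 ± 92.2 RPM and at 647.2 ± 22.6 against 903.3 ± 214.1 RPM, with miR-34c-5p at 636.1 ± 118.2 against 769.1 ± 231.8 RPM. The let-7 family had an adjusted p of 0.234, the astroglia-associated list 0.204, and the reported regulators of the glucocorticoid receptor 0.308. In that last list miR-18a-5p was at 294.6 ± 46.7 against 377.6 ± 133.2 RPM and miR-124-3p, the most neuron-specific of them, at 238.6 ± 28.4 against 229.0 ± 50.8 RPM. The neural progenitor and neurogenic list had 7 positive and 10 negative log2 folds among 17, with a median of -0.01 and an adjusted p of 0.715. For the miR-17-92 and paralogous clusters, which promote proliferation, the adjusted p was 0.662, with miR-93-5p at 3053 ± 249 against 3480 ± 518 RPM and miR-92a-3p at 2038 ± 151 against 1926 ± 884 RPM. The cell-cycle restraining list (0.946), the hypoxia and stress list (0.715), the activity-regulated list (0.946), the oligodendrocyte lineage list (0.92), the muscle list (0.92) and the liver list (0.637) gave adjusted p values far from the threshold. The pluripotency clusters and the cluster of miR-183, miR-96 and miR-182 had no tested member, with no more than 0.416 and 2.50 RPM in any library.

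Arm usage was compared for 155 precursors with both arms past the filter. None changed in limma at an adjusted p under 0.05, and 9 had an unadjusted p under 0.05, where 7.75 would be expected by chance. For miR-335 the log2 ratio of the 5p over the 3p arm was higher in GDE by 0.54 (SE 0.21; limma, adjusted p = 0.674).

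The composition of the libraries was compared because it can set the size of fold changes. The RPM of all rows summed to 253175 ± 10267 in GDE and 263885 ± 12551 in Control (exact two-sided permutation p = 0.4). With no further scaling, the median log2 fold over all tested miRNAs was -0.067 in limma. With DESeq2-type size factors it was 0.014. Signs and medians of small log2 folds carry this offset. The 10 most abundant miRNAs took 32.7 ± 0.808% of the RPM in GDE and 31.6 ± 1.17% in Control (n = 3 each; exact two-sided permutation p = 0.4). The most abundant one took 3.70 ± 0.12% against 3.53 ± 0.164% (exact p = 0.3), and predicted miRNAs took 0.525 ± 0.0756% against 0.545 ± 0.0706% (exact p = 0.8). In GDE 1308 ± 30.8 miRNAs were detected, against 1326 ± 5.69 in Control (exact p = 0.4). Over the 9 such comparisons the lowest adjusted p was 0.514, with 0.1 the smallest p that the exact test can give.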

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

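Settings with both of GDE replicate 3 and Control replicate 1 set aside, TMM factors and robust variance in limma, the host gene sets and the removal of miRNAs that switch across groups were chosen after seeing the data. edgeR's robust test with TMM, fixed beforehand for counts, was added as an alternative on the recovered tags. The 11 miRNAs named by the rule kept the sign of their log2 fold in all 250 refits, and no result reversed. Except for miR-335-5p, the groups of these miRNAs did not overlap, and most were picked by lowest p in the same data. For them, leaving out libraries or changing the pseudocount, filter or variance method cannot flip the sign. The kept sign in those refits is therefore no evidence that their folds are stable. miR-335-3p had a log2 fold of -1.34 to -0.67 and miR-335-5p of -0.78 to -0.04 over the alternatives, with adjusted p of 0.211 to 0.822 and 0.466 to 0.999. The count of 2 miRNAs became 1 with at least 100 tags in 3 libraries and 1 with miRBase names alone. Both of these settings leave the predicted miRNA untested. The count was 1 in limma-voom and 4 in DESeq2, both main miRNAs among the 4. It was 2 to 3 when libraries were left out in turn, and 3 with the 2 libraries set aside. The count of 5 lists became 0 with an estimated correlation and 0 with the 2 libraries set aside, and ranged from 0 to 4 when libraries were left out in turn, with 4 without GDE replicate 1, 3 without GDE replicate 2, 2 without GDE replicate 3, 0 without Control replicate 1, 3 without Control replicate 2 and 4 without Control replicate 3. The count of 1 genomic cluster became 2 with no filter and 0 with the 2 libraries set aside, and ranged from 0 to 2 when libraries were left out. Beyond the smaller number of tested miRNAs or libraries, the cause was not tested. Of 1426 refitted folds of the other named miRNAs, 95 moved by more than 1 SD. Whether any of these other folds changed sign was not recorded. Libraries of the same number did not deviate together, with correlations of -0.03, -0.12 and -0.03, so the numbers are not taken as pairs. With a replicate block 2 miRNAs were called, both of them those of the main test, and the neuron-enriched list was lost (camera, adjusted p = 0.0571). Depth limits miRNAs under about 0.25 RPM, the level that a count of 0 allows.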

Other observations

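The tests of explanations in this part, the miRNAs named in them and the sets of miRNAs within 1 host gene were chosen after the results were seen. The counts over other splits of the libraries were planned, but what they should show was also stated only after the results were seen. Of 20 host gene sets, 2 passed in camera with a preset correlation. The miRNAs of Htr2c, the serotonin receptor 2C gene on chromosome X, between 147010601 and 147158321, had a median log2 fold of 1.55 over 4 members, all positive (camera, adjusted p = 0.0052; adjusted p = 0.772 with an estimated correlation). miR-1298-5p, their most abundant member, was at 55.3, 17.1 and 131.0 RPM in GDE and at 5.32, 10.5 and 29.6 RPM in Control. The set in Mirg, of the Dlk1-Dio3 locus, had a median of 0.20 over 10 members (camera, adjusted p = 0.0307; adjusted p = 0.772 with an estimated correlation).

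The Htr2c miRNAs may come from choroid plexus cells, which express Htr2c and also miR-204 and miR-211, both in the list fixed beforehand. A like order of the 6 libraries was noticed first and only then measured, so the relation to miR-204 and miR-211 restates what was seen and its p values are no evidence (Spearman rho 0.94, exact permutation p = 0.0167, adjusted 0.0666 over 4 relations; Pearson r 0.96, exact permutation p = 0.00278, adjusted 0.0111; r 0.84 without the 2 libraries farthest from the median). The endothelial and mural list had a rho of 0.89 and an r of 0.91 with the Htr2c miRNAs, the microglia and leukocyte list 0.54 and 0.45, and the erythroid list 0.09 and 0.12, with Spearman adjusted permutation p of 0.0666, 0.396 and 0.919, Pearson adjusted permutation p of 0.0222, 0.499 and 0.818, and an r without these 2 libraries of 0.73, -0.34 and -0.24. The 4 arms of miR-34b and miR-34c, in the same list as miR-204 and miR-211, went the other way. Their mean log2 level was 8.56 ± 0.19 in GDE and 8.9 ± 0.35 in Control, with overlapping libraries (exact permutation p = 0.2). Over the 11 tested members of that list, 6 log2 folds were positive and 5 negative. Among the positive ones, miR-449a-5p was at 180.8 ± 43.6 RPM in GDE and 122.5 ± 26.4 RPM in Control, with overlapping groups (limma, adjusted p = 0.561). A differing amount of choroid plexus cells stays open. A lower share of neural cells would raise all other types alike. The difference of the Htr2c miRNAs exceeded that of the endothelial and mural list by 1.04 log2 units and that of the miR-34b and miR-34c arms by 1.72. Libraries overlapped in both (exact permutation p = 0.2 for each). The mean log2 level, GDE minus Control, differed by 0.33 for the endothelial and mural list and by 0.60 for the microglia and leukocyte list (exact permutation p = 0.1 for each). It differed by 0.41 for the erythroid list and by -0.35 for the miR-34b and miR-34c arms (exact permutation p = 0.2 for each). So a lower share of neural cells cannot be told apart either, and an effect of the exposure was not tested.

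miR-297c-5p is present in GDE and nearly absent in Control, and 2 technical explanations were weighed. Tags of the near-identical miR-297a-5p and miR-297b-5p could have been assigned to it. Their sum was lower in GDE by 73.4 RPM (237.8 ± 27.6 against 311.2 ± 64.0 RPM; exact permutation p = 0.3), the direction that such an assignment would give. The libraries overlapped in this sum, and miR-297c-5p held more, 169.7 RPM, so this explanation cannot be decided. The other copies cannot be told apart as donors, since the list without miR-297c-5p was lower by 649.1 RPM. Single miRNAs also switch between libraries without regard to group, which may be the same event. A gap of at least 3 log2 units split libraries across the groups for 3 miRNAs, miR-744-5p, miR-532-5p and miR-532-3p, while miR-744-3p stayed within 25.9 to 30.5 RPM as miR-744-5p ranged from 1.70 to 230.1 RPM. miR-532-5p and miR-532-3p are arms of the same precursor but were not high in the same libraries. At their lowest, miR-744-5p and miR-532-5p were still at 1.70 and 4.04 RPM, unlike miR-297c-5p, whereas miR-532-3p fell to 0.085 RPM. A difference between litters and an effect of the exposure stay open and were not tested.

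The most abundant miRNA, miR-9b-3p, had nearly the same number of tags in every library, with an SD of 189.0 tags where a constant share of the library would give 2131. A stable share would vary only in ways unrelated to the library totals. Of all 720 pairings of the RPM of miR-9b-3p with the totals, the real one gave the lowest SD of log2 tags (exact permutation p = 0.00139, the smallest possible, adjusted 0.0278 over the 20 most abundant miRNAs). The steady tags prompted this test, so its p value restates what was seen. It argues neither against a share that varies in ways unrelated to the totals nor for another explanation, and such a share stays open. An exactly constant share is a narrower case, since counting error has an SD of only 334.8 tags. The SD of 189.0 tags against 2131 argues against an exactly constant share, for miR-9b-3p alone. A ceiling on the tags counted per miRNA is a candidate explanation that stays open, since the other 17 miRNAs above 5000 RPM had an exact permutation p of 0.0722 for their median SD, against 0.235 for the 110 miRNAs from 100 to 1000 RPM. The 4 next most abundant miRNAs had low unadjusted values in the same test, with an exact permutation p of 0.0181 for let-7c-5p, 0.00972 for miR-99a-5p, 0.00556 for miR-9-5p and 0.0306 for let-7b-5p, and adjusted p of 0.0556 to 0.122. A ceiling would hide differences between the groups in the most abundant miRNAs, and other causes were not tested.

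With 10 splits of the 6 libraries into 3 and 3, no count can have a share under 0.05. The real split gave 2 miRNAs and the highest other split 1, so 1 split reached the real count. For lists these were 5 and 5, with 2 splits reaching it, for genomic clusters 1 and 4, with 6 splits, for host gene sets 2 and 4, with 5 splits, and for arm ratios 0 and 0, with 10 splits.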
